A study of Mus musculus with 16 samples.

How the data were processed

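RNA from the palate of mouse embryos was measured on 16 one-colour Affymetrix expression arrays. The labels place the arrays in 4 groups by embryonic day and genotype. Mutants carried a floxed Erk2 gene deleted by Wnt1-Cre, a driver active in neural crest cells, and controls carried the floxed gene without Cre, per the genotype labels, while the sample titles call the controls wild-type. There were 3 mutants and 3 controls at E13.5, and 5 mutants and 5 controls at E14.5. The E14.5 arrays carry a batch label, with replicates 1 and 2 in batch 1 and replicates 3, 4 and 5 in batch 2 in both genotypes. The E13.5 arrays carry no batch label. The series description speaks of primary palatal mesenchymal cells and the labels' extraction protocol of palate mesenchyme tissue, so which of these was lysed stays open. The labels do not say how many embryos one array holds, and p-values measure only the spread between these samples.

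The deposited values are log2 expression values for 45101 probe sets, and the authors made them with GCRMA, per the submitters' processing notes. The version and settings of GCRMA are not given in the sources used here. The value distributions differed between the stages: array medians were 3.39 to 3.44 at E13.5 and 1.63 to 1.66 at E14.5. Whether the stages were normalized in separate runs is not stated. Within E13.5 the array medians were 3.42 to 3.44 in mutants and 3.39 to 3.40 in controls, without overlap. Values within a stage were compared as deposited, and differences between stages carry the shift between stages.

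Genes were named through the platform annotation. It gave 1 gene for 34958 probe sets and several for 932. It named none for 9211. Of all probe sets, 64 were controls. Each gene was represented by its probe set with the highest mean over all arrays, which gave 18195 genes. Genes were tested if at least 3 arrays reached a log2 value of 4, which left 11116 genes. The level of the targeted gene itself was not analysed here, so the genotype labels have no expression check. For arrays, the number of arrays limits the precision.

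Differences were tested with limma 3.58.1 in R 4.3.3. One lmFit and eBayes fit held all 16 arrays with the 4 groups and the labelled batch within E14.5, so that the groups shared one estimate of spread per gene. Contrasts were mutant minus control at each stage, the difference between these effects, and E14.5 minus E13.5 in each genotype. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 11116 genes, and errors are moderated standard errors. Gene lists for signalling, metabolism, differentiation and other cell types were fixed before the data were examined. Of 35 such lists, 33 held at least 5 tested genes and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. Camera sets the members of a list against all other genes. With an estimated correlation, no list passed in any contrast. The fry test, which asks whether the members move one way on balance, was run beside it.

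Named genes followed a rule fixed before the data were examined. It took, per contrast, up to 10 genes with the largest rise and 10 with the largest fall among called genes whose arrays did not overlap between groups, without the overlap condition for the difference between stages. Overlap of E14.5 arrays was judged after the fitted batch effect was removed. The rule added up to 4 members per list with the smallest p. RIKEN clones and predicted genes were left out. The targeted gene, first in the rule, is an exception, and for the changes between stages no falls and only some of the rises are named. Genes outside this rule appear in the closing section and were chosen after their values were seen.

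The scripts were tested on simulated arrays built from the fitted means and spreads of the 11116 genes, with 200 genes changed. At E13.5, 40.9% of genes changed 1.25-fold, 80.6% of those changed 1.5-fold and 96.2% of those changed 2-fold were recovered, and 5.54% of calls were false. At E14.5 the shares were 62.7%, 91.5% and 98.3%, with 6.30% of calls false. Simulated noise was normal and independent between genes. Alternatives covered the filter, the choice of probe set, the normalization, the variance model, the batch term, a replicate block and leaving out each array. After the data were seen, a term for sex, a term for the signal difference between the ends of beta-actin, and a fit without E14.5 controls 1 and 3 were added. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.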

Results

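The series asked how the loss of Erk2, a kinase of the RAS and MAPK signalling pathway, in neural crest cells affects the metabolism of the mesenchyme that forms the palate. Gene expression was profiled in mutants (floxed Erk2 with Wnt1-Cre) and controls (floxed Erk2 alone) at E13.5 (3 arrays per genotype) and E14.5 (5 arrays per genotype). Arrays of one group correlated at 0.993 to 0.997 over 11116 genes, and no pair held identical values. Sex-linked transcripts placed all 6 E13.5 arrays as female. At E14.5, 3 of 5 mutants and 1 of 5 controls were female. The sex of the embryos was therefore uneven between the E14.5 genotypes.

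At E13.5 few single genes differed between genotypes. Gria1, a glutamate receptor subunit, fell by 1.14 ± 0.15 on the log2 scale in mutants (moderated SE, n = 3 and 3), to 0.453 times the control level (adjusted p = 0.0047, limma). The chemokine Cxcl5 fell by 0.95 ± 0.08, Gabrb2, a GABA receptor subunit, fell by 0.71 ± 0.09, and the Iroquois transcription factor Irx5 fell by 0.49 ± 0.08. Trim12c, Ankrd29, Cwc22, Pm20d2 and Slitrk4 also fell, by 0.69, 0.65, 0.64, 0.51 and 0.44. The anion transporter Slc26a7 rose by 0.72 ± 0.12 and Commd9 by 0.60 ± 0.08. With the mean over the probe sets of a gene Commd9 was at 0.19 and did not pass (adjusted p = 0.40), and Trim12c was at −0.41. The calls of Irx5, Slitrk4, Slc26a7 and Pm20d2 were lost under 18, 16, 12 and 11 alternatives. In all, 11 genes passed, 2 higher and 9 lower in mutants, and 1060 had an unadjusted p under 0.05 where 555.8 would by chance. With each array centred on its median the split was 3 higher and 6 lower. The count rested on single arrays: it was 35 without mutant 2, 6 without mutant 1, 6 without mutant 3, 6 without control 3 and 7 without control 1. The number of lists shifted was 14, and 8 without mutant 2. The 5' minus 3' signal of beta-actin was −1.01 ± 0.04 in mutants and −1.19 ± 0.16 in controls (SD, n = 3 and 3, exact permutation p = 0.20, two-sided). With that signal as a term 6 genes passed, all 6 among the 11, and 10 lists (6 higher, 4 lower).

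Among the lists, genes of bone formation were lower in E13.5 mutants: 15 of 18 measured osteogenic genes lay below controls, with a median log2 difference of −0.21. None passed over all genes tested, and adjusted over the list alone 3 fell and 1 rose. Ibsp (bone sialoprotein) was at −1.31 ± 0.41, Tnfrsf11b (osteoprotegerin) at −1.02 ± 0.31 and Ifitm5 at −0.89 ± 0.25, and without mutant 1 Ibsp was at −0.71 and Tnfrsf11b at −0.67. With the mean over probe sets Ibsp was at −0.83. The camera test placed the list below other genes (adjusted p = 0.0087), with adjusted p = 0.49 with an estimated correlation. That call was lost without mutant 1 (camera adjusted p = 0.11) and without control 1 (0.18). The list of palatal mesenchyme transcription factors was lower in 23 of 28 members (camera adjusted p = 0.040, and adjusted p = 0.39 with an estimated correlation). Its members Foxf1, at −0.41 ± 0.09, and Osr2, at −0.32 ± 0.09, did not pass. This call was lost without mutant 2 (camera adjusted p = 0.13), control 1 (0.053), control 3 (0.17) or E14.5 mutant 2 (0.054), with the actin signal as a term (0.057), with array weights (0.084) and without the batch term (0.0501). Centred on the array medians it passed, at a median of −0.07 where the values as deposited gave −0.13. By fry the palatal transcription factors passed (adjusted p = 0.041) and the osteogenic list did not (0.17).

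Several metabolic lists also lay lower in E13.5 mutants, each by a small amount. All 20 measured genes of cholesterol biosynthesis were lower, with a median log2 difference of −0.12 (camera adjusted p = 3.1e-04, adjusted p = 0.39 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, was at −0.19 ± 0.05 and passed adjusted over the list alone (1 gene), though not over all genes tested. Of 21 genes of fatty acid and triglyceride synthesis, 19 were lower, among them Fasn at −0.31 ± 0.10 (camera adjusted p = 0.0084, adjusted p = 0.39 with an estimated correlation). Of 18 glycolysis genes, 17 were lower, led by Aldoc at −0.51 ± 0.13 and Pfkfb3 at −0.34 ± 0.10. Both passed adjusted over the list alone (2 genes), and the list had a camera adjusted p = 0.0099 and adjusted p = 0.39 with an estimated correlation. It did not pass without mutant 2 (0.096) or control 1 (0.075). With the mean over probe sets neither glycolysis (0.086) nor fatty acid synthesis (0.086) passed. Oxidative phosphorylation went the other way, with 26 of 42 genes higher and a median of 0.02 (camera adjusted p = 0.0019, adjusted p = 0.49 with an estimated correlation). It did not pass after a further quantile normalization (0.081) or with no filter on low values (0.31). By fry cholesterol biosynthesis (adjusted p = 0.037) and glycolysis (0.046) passed. Fatty acid synthesis (fry adjusted p = 0.059) and oxidative phosphorylation (0.67) did not. The median of all genes was −0.04 at E13.5, and the tallies rest on this scale. With each array centred on its median, 17 of 20 cholesterol genes (median −0.05, Hmgcs1 at −0.12), 16 of 21 fatty acid genes (−0.05) and 12 of 18 glycolysis genes (−0.02) were lower. Of the oxidative phosphorylation genes 40 of 42 were then higher (0.09), and the 4 lists passed. The list of ERK targets was not shifted (camera adjusted p = 0.62): 17 of 21 members lay below controls, including Fosl2 at −0.37 ± 0.09 and Egr1 at −0.42 ± 0.14 (−0.27 without mutant 2). Fosl2 was at −0.13 with the mean over probe sets. With each array centred on its median 8 of 21 lay below controls (median 0.01), and with the actin signal as a term 10 of 21 did.

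Markers of other tissues moved at E13.5 as well. Skeletal muscle genes were higher in mutants in 27 of 28 cases, with a median of 0.60 (camera adjusted p = 3.5e-14, adjusted p = 0.39 with an estimated correlation), and the muscle regulator Myod1 was at 0.57 ± 0.25. Cartilage genes had a median of 0.35, with Epyc at 1.30 ± 0.36 and Matn1 at 1.10 ± 0.28. That list had a camera adjusted p = 1.7e-04 and adjusted p = 0.39 with an estimated correlation, and adjusted over the list alone 4 members rose and 1 fell. It did not pass without mutant 2 (camera adjusted p = 0.0504). Neuronal genes were higher in 14 of 15 cases (camera adjusted p = 1.9e-05, adjusted p = 0.39 with an estimated correlation). Their mean was 5.45 ± 0.51 in mutants and 5.04 ± 0.12 in controls (SD, n = 3 and 3), but 5.16 in mutants without mutant 2, where the list did not pass (camera adjusted p = 0.074). None of these genes passed over all genes tested. By fry the muscle, cartilage and neuronal lists did not pass (adjusted p = 0.35, 0.35 and 0.39).

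**Figure D1:**
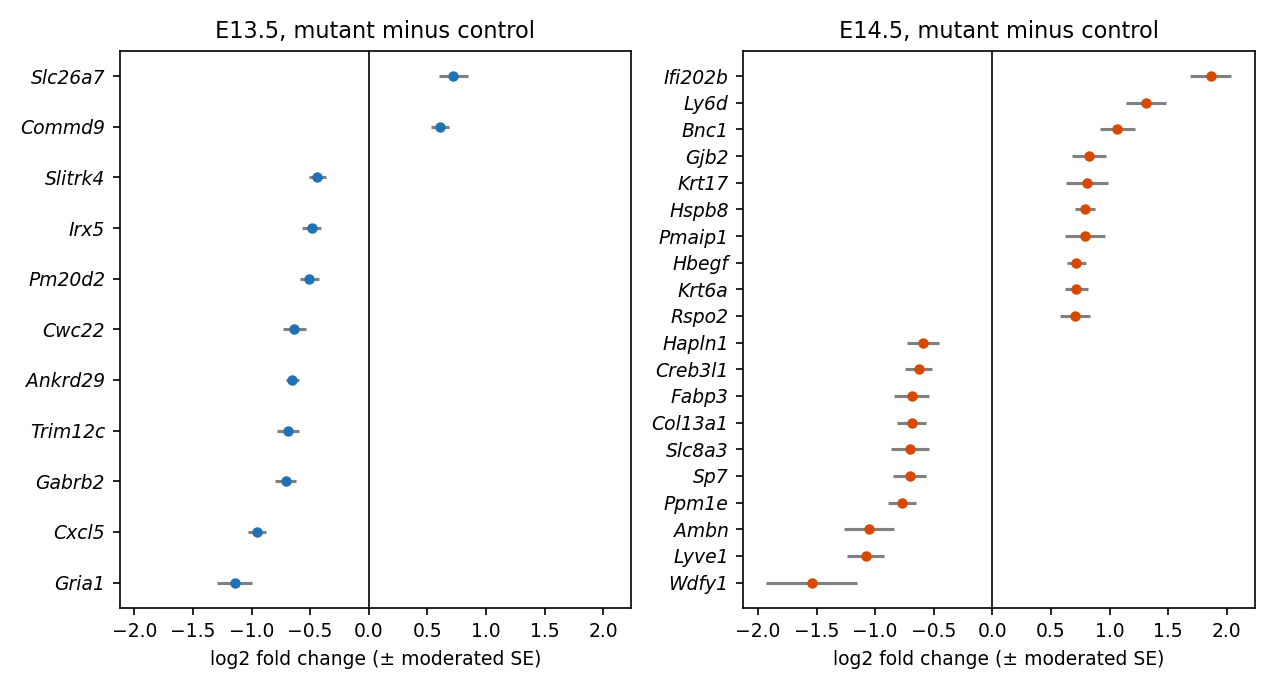
Log2 fold changes between mutants and controls with moderated standard errors at E13.5 (left) and E14.5 (right). Drawn are the called genes with the largest rises and falls under the fixed rule, without the members it adds per list. Among the genes drawn, Gria1 lies lowest at E13.5 (−1.14), and Ifi202b highest at E14.5 (1.86).

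At E14.5, 13 of 29 oral epithelium genes rose and 8 of 18 osteogenic genes fell in mutants. The interferon-inducible gene Ifi202b rose 3.64-fold (log2 1.86 ± 0.18, n = 5 and 5, adjusted p = 3.7e-04, limma). Ly6d, a surface protein of stratified epithelia, rose 2.48-fold, and Bnc1, a zinc finger protein of keratinocytes, 2.09-fold. Gjb2 (connexin 26), the keratin genes Krt17 and Krt6a, the growth factor gene Hbegf, Hspb8, the cell death gene Pmaip1 and the WNT potentiator Rspo2 rose 1.63- to 1.77-fold. Among the genes that fell, Wdfy1 decreased by 1.54 ± 0.38, the lymphatic marker Lyve1 by 1.08 ± 0.16, the enamel matrix gene Ambn by 1.05 ± 0.21 and the bone transcription factor gene Sp7 by 0.70 ± 0.14. Ppm1e, Slc8a3, Col13a1, Fabp3, Creb3l1 and Hapln1 fell by 0.59 to 0.77. In batches 1 and 2 the log2 changes were −0.11 and −1.07 for Fabp3, 0.40 and 1.05 for Pmaip1, −0.46 and −0.86 for Slc8a3, and −0.37 and −0.80 for Creb3l1. With the mean over probe sets Rspo2 was at 0.29 (adjusted p = 0.080), Wdfy1 at −0.89 (0.055) and Hapln1 at −0.32 (0.36), which did not pass, and Fabp3 at −0.36 and Slc8a3 at −0.37. Krt17 was at 0.53 without controls 1 and 3 and did not pass (adjusted p = 0.099). The calls of Wdfy1, Slc8a3 and Hapln1 were lost under 24, 18 and 18 alternatives. In all, 292 genes passed, 164 higher and 128 lower, and 46 of them changed at least 1.5-fold. After the fitted batch effect was removed, the arrays of the genotypes did not overlap for 545 of all 11116 genes (4.90%), and 234 of the 545 were among the 292. Chance gives 0.794% in 5 against 5 arrays for values without such a removal, so that share is only a guide. With each array centred on its median, 128 were higher and 155 lower. The count was 64 with the E14.5 arrays alone (63 of them among the 292), 130 after a further quantile normalization (127), 155 with array weights (153) and 184 with no filter on low values (158).

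The fit with batch 1 alone called 31 genes, 12 of them among the 292, and that with batch 2 alone 128, 89 of them among the 292. The count was 143 with sex as a term within E14.5, and 131 of those were among the 292. It was 201 without controls 1 and 3, and 124 of the 201 were among the 292. Controls 1 and 3 had the lowest muscle and ERK target means of the controls. The count was 105 without mutant 1, 194 without mutant 4, 122 without mutant 5, 137 without control 2, 154 without control 3 and 188 without E13.5 control 1.

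Oral epithelium genes had the smallest camera p of the lists at E14.5. All 29 were higher in mutants, with a median of 0.37, and 13 rose (24 adjusted over the list alone). Sfn rose by 0.64 ± 0.07, Krt14 by 0.62 ± 0.09, Pkp3 by 0.63 ± 0.12 and the simple-epithelium keratin Krt18 by 0.49 ± 0.06. The list had a camera adjusted p = 3.3e-18 and adjusted p = 0.14 with an estimated correlation. The per-array mean of the list was 6.68 ± 0.13 in mutants and 6.30 ± 0.05 in controls (SD, n = 5 and 5). Skeletal muscle genes were also higher, all 28 with a median of 0.48, but none passed (camera adjusted p = 7.6e-05, adjusted p = 0.81 with an estimated correlation). The list did not pass without control 1 (median 0.24, camera adjusted p = 0.092), and without controls 1 and 3 its median was −0.02 (camera adjusted p = 0.69). Controls 1 and 3 had the lowest muscle means at E14.5 (4.44 and 4.42, other controls 5.43 to 5.78). Leaving them out by itself shrinks the difference, so it shows only how far the rise rests on them. Without control 3 alone the median was 0.28, with E14.5 batch 1 alone 1.07, and with batch 2 alone 0.12, where it did not pass (camera adjusted p = 0.52). By fry the epithelial list passed (adjusted p = 0.0017) and the muscle list did not (0.38).

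Bone genes were lower again. Of 18 osteogenic genes, 8 fell and 10 did not pass (11 fell and 1 rose adjusted over the list alone), and the median was −0.35. Dmp1 and Phex, genes of mineralizing bone cells, changed by −1.36 ± 0.26 and −1.22 ± 0.23, and Mef2c by −0.35 ± 0.06. In batches 1 and 2 these were −0.53 and −1.91 for Dmp1, −0.67 and −1.59 for Phex, and −0.21 and −0.44 for Mef2c. The list had a camera adjusted p = 2.1e-09 and adjusted p = 0.20 with an estimated correlation. Of 29 extracellular matrix genes, 4 fell: Ogn, Bgn, Sparc and Lox, by 0.17 to 0.28 (6 adjusted over the list alone, camera adjusted p = 7.9e-04, adjusted p = 0.40 with an estimated correlation). With batch 2 alone that list did not pass (camera adjusted p = 0.26). By fry it did not pass either (adjusted p = 0.15), while the osteogenic list did (0.017). The collagen prolyl hydroxylase genes P4ha1 and P4ha2, in other lists, fell by 0.35 ± 0.07 and 0.36 ± 0.09, Foxf1 by 0.34 ± 0.07 and Sox6 by 0.33 ± 0.07. In batches 1 and 2 Bgn was at −0.28 and −0.13, Sparc at −0.14 and −0.28, and P4ha1 at −0.23 and −0.43. With the mean over probe sets neither Sparc, at −0.14, nor Foxf1, at −0.14, passed. The calls of Lox, P4ha2, Sparc and Bgn were lost under 25, 22, 21 and 20 alternatives.

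ERK target genes were higher in E14.5 mutants. Of 21, 5 rose and 16 did not pass (10 rose adjusted over the list alone), with a median of 0.20, a camera adjusted p = 7.0e-06 and adjusted p = 0.17 with an estimated correlation. Ier3 rose by 0.55 ± 0.08, Fos by 0.42 ± 0.10, the pathway inhibitor Spry1 by 0.31 ± 0.08 and the ERK phosphatase gene Dusp4 by 0.30 ± 0.04. Spry1 was at 0.52 in batch 1 and 0.18 in batch 2, and its call was lost under 22 alternatives and that of Fos under 15. The growth factor Fgf9 rose by 0.32 ± 0.06. Immediate early and heat shock genes, which tissue handling can induce, moved the same way: 4 of 16 rose (Socs3, Dusp1, Ier5 and Hspb1, by 0.21 to 0.39) and the list had a camera adjusted p = 0.0096 and adjusted p = 0.20 with an estimated correlation. It did not pass without controls 1 and 3 (camera adjusted p = 0.13), with a median of 0.13 where all arrays gave 0.10, nor with sex as a term (0.053) or with batch 1 alone (0.15). Without controls 1 and 3, which had the lowest ERK target means at E14.5 (6.02 and 5.91), the median of the ERK targets was 0.14. There 2 genes passed. With sex as a term the median was 0.18 and 2 genes passed. Ier5 was at 0.13 with the mean over probe sets and did not pass (adjusted p = 0.36), and the call of Hspb1 was lost under 19 alternatives.

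Of the metabolic lists, oxidative phosphorylation alone passed at E14.5, and its call rested on single arrays. Its genes were higher in 39 of 42 cases, by a median of 0.05, and Ndufv1 rose by 0.15 ± 0.03 (camera adjusted p = 0.0096, adjusted p = 0.79 with an estimated correlation). The list did not pass without mutant 1 (0.090), mutant 2 (0.064), control 1 (0.075), control 2 (0.080) or controls 1 and 3 (0.063), nor with sex as a term (0.16). The median was 0.13 with batch 1 alone and under 0 with batch 2 alone (camera adjusted p = 0.74). The call of Ndufv1 was lost under 20 alternatives. Cholesterol biosynthesis (camera adjusted p = 0.89) and glycolysis (camera adjusted p = 0.51) were not shifted. Endothelial genes were lower in 19 of 22 cases (median −0.14, camera adjusted p = 1.3e-05, adjusted p = 0.37 with an estimated correlation), with Erg at −0.305 ± 0.087 and Cdh5 at −0.27 ± 0.08 (−0.18 and −0.16 with the mean over probe sets), and none passed. By fry neither oxidative phosphorylation (adjusted p = 0.12) nor the endothelial list (0.10) passed.

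**Figure D2:**
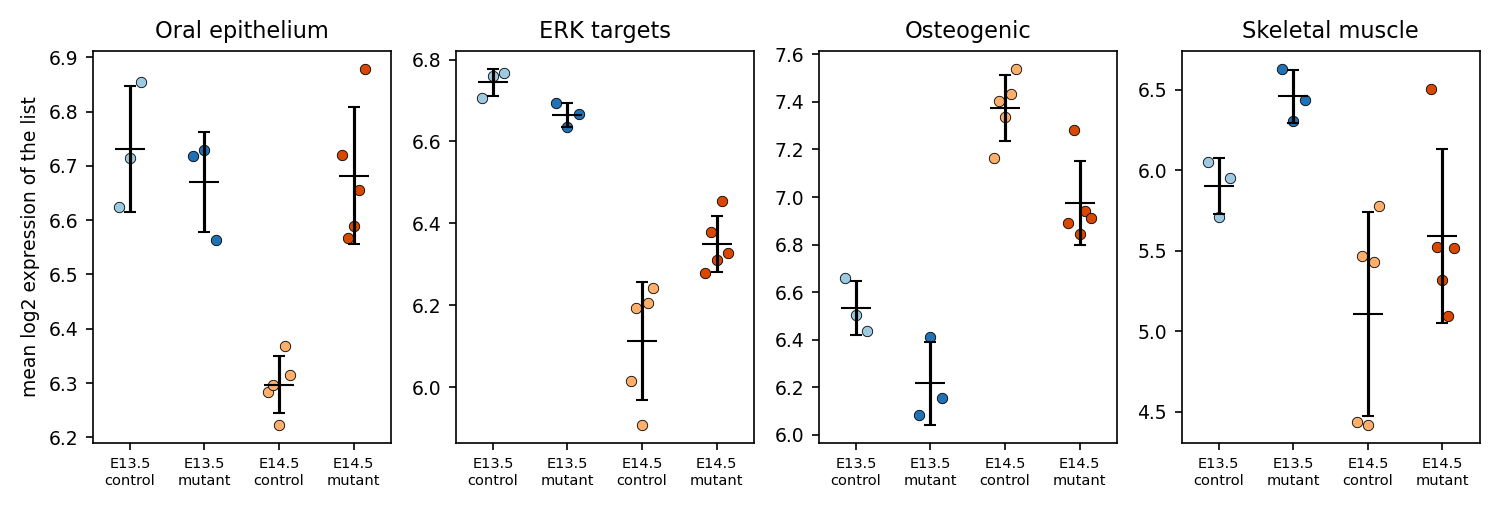
Mean log2 expression of 4 gene lists on each array by group, with the group mean and SD in black. The E14.5 mutants lie above the E14.5 controls for oral epithelium (means 6.68 and 6.30), and E13.5 and E14.5 values carry a shift in scale.

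The genotype effects were then compared between stages, a comparison of independent arrays. Across genes the log2 fold changes at E13.5 and E14.5 had a Pearson r of 0.27 (jackknife SE over arrays 0.11), described only, since genes are not independent replicates. Of 9 genes lower at E13.5 and 128 lower at E14.5, 4 were shared (Cxcl5, Gabrb2, Irx5 and Slitrk4). No gene was higher at both.

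The difference between the effects passed for 13 genes, 11 more positive at E14.5 and 2 more negative. Ifi202b differed by 1.93 ± 0.29, Krt6a by 0.94 ± 0.16, Sfn by 0.74 ± 0.11 and the cytokine signalling inhibitor Socs3 by 0.48 ± 0.08. Cwc22 differed by 0.74 ± 0.12 and Ankrd29 by 0.55 ± 0.07, both of which fell at E13.5 and did not pass at E14.5. Cxcl5 differed by 0.70 ± 0.10 and fell at both stages. Commd9 (−0.56 ± 0.10) and Gzmm (−0.45 ± 0.08) were more negative at E14.5. Gzmm lay near the floor there, with the 2 lowest arrays at 1.01 and 1.17 in mutants and 1.23 and 1.29 in controls. The E14.5 array medians over all probe sets were 1.63 to 1.66. An effect of genotype on Gzmm at E14.5 could therefore not be seen, and its difference is not a measured change in effect. With the mean over probe sets Commd9 was at −0.10 and did not pass (adjusted p = 0.69). The calls of Gzmm, Socs3, Commd9, Depdc7, Cwc22 and Krt6a were lost under 22, 22, 21, 20, 16 and 14 alternatives. Oral epithelium (median difference 0.43, camera adjusted p = 3.6e-12, adjusted p = 0.22 with an estimated correlation) and ERK targets (0.27, camera adjusted p = 1.9e-05, adjusted p = 0.22 with an estimated correlation) were more positive at E14.5. The ERK targets Ier3 and Egr1, with differences of 0.68 ± 0.13 and 0.77 ± 0.18, did not pass. With each array centred on its median, 7 genes were more positive and 3 more negative. The count was 3 without E13.5 mutant 3, E13.5 control 2 or E13.5 control 3, 7 without E13.5 mutant 1 or E14.5 control 4, 8 without E14.5 mutant 3 and 20 without E14.5 control 1.

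From E13.5 to E14.5 the osteogenic list was higher relative to other genes in controls (camera adjusted p = 2.5e-07, adjusted p = 0.33 with an estimated correlation), where 12 of 18 members rose and 6 fell. In mutants 11 rose and 6 fell (camera adjusted p = 1.4e-05, adjusted p = 0.34 with an estimated correlation). Relative to the median of all genes, Dmp1 was higher by 7.75, the collagenase gene Mmp13 by 6.06, Ibsp by 4.97, and the cilium genes Dynlrb2, Deup1 and Foxj1 by 6.58, 5.40 and 4.81. The airway secretory gene Bpifa1 was higher by 4.65. As deposited, Dmp1 rose by 7.12 in controls, of which the 2 lowest at E14.5 were at 8.06 and 8.57. Its E13.5 signal thus lay near the floor, and the size of its rise is not exact. In mutants, relative to their median, Dmp1 was higher by 6.32, Mmp13 by 5.79, Ibsp by 5.78, Dynlrb2 by 6.46 and Foxj1 by 4.75. Dmp1 was near the floor in E13.5 mutants too, with a rise of 5.76 as deposited and the 2 highest E14.5 mutants at 8.41 and 7.28. The medians of all genes were −0.63 in controls and −0.56 in mutants. In controls 9618 genes passed (1294 higher, 8324 lower) and in mutants 9481 (1484 higher, 7997 lower). After a further quantile normalization 3688 were higher and 4190 lower in controls, and 3756 higher and 4056 lower in mutants. Low signals shrank most: the weakest spiked control transcript, bioB, was at 2.61 ± 0.19 on E13.5 arrays and 1.37 ± 0.09 on E14.5 arrays, and the strongest, cre, at 11.3 ± 0.19 and 11.5 ± 0.11 (SD, n = 6 and 10). In controls the median change was −1.95 in the 2779 genes with the lowest mean level and −0.19 in the 2779 with the highest. The number of genes that changed between stages therefore includes a difference in the scale of the arrays. The camera p of the osteogenic list, set against all other genes, may hold part of that difference too.

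**Figure D3:**
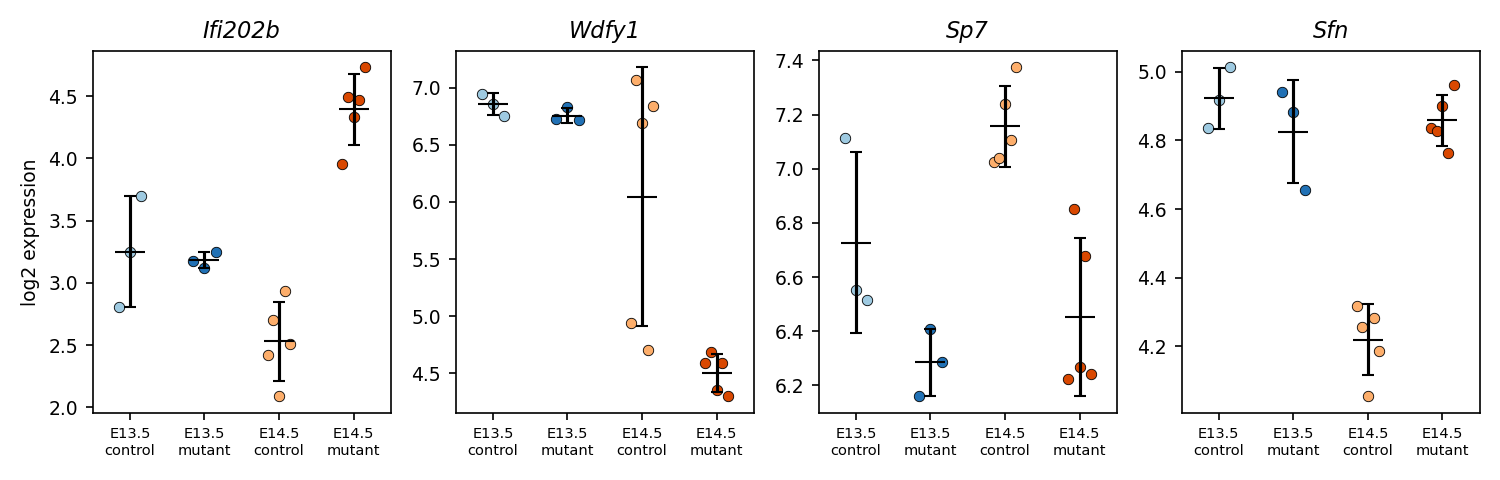
Log2 expression on each array for Ifi202b, Wdfy1, Sp7 and Sfn by group, with group mean and SD. The E14.5 mutants and controls separate for Ifi202b, while 2 E14.5 controls lie near the mutants for Wdfy1.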

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

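The tests of sex, of controls 1 and 3, of the parts of the epithelium, of handling, of Wdfy1 and of simulated values were chosen after the results were seen, and those of the epithelial term and of the other splits before. Of the 3 weighed patterns the first concerns epithelium. All 29 oral epithelium genes were higher in E14.5 mutants, by a median of 0.37. A larger share of epithelial cells of every kind may raise all such genes. The mean of 10 general epithelial genes was higher in mutants by 0.30 and that of 10 genes of stratified epithelium by 0.53 (exact permutation p = 0.0079 for each), a difference of 0.24 (exact permutation p = 0.016, all two-sided). The mean of the whole list already separated these arrays (6.57 to 6.88 in mutants, 6.22 to 6.37 in controls). The p of each part therefore adds little. Other cells may express the general genes and damp their rise, so a larger share of all epithelium, a larger share of stratified epithelium and a change in expression by genotype cannot be told apart. With sex as a term the median was 0.37, and without controls 1 and 3 it was 0.34, so neither is the whole of it.

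The second pattern is that ERK targets were higher in E14.5 mutants, by a median of 0.20, although a kinase of that pathway had been deleted in neural crest cells. Controls 1 and 3 had the lowest ERK target means at E14.5, so leaving them out by itself shrinks the difference. Without them the median was 0.14 and the list still passed (camera adjusted p = 0.0048). With sex as a term it was 0.18, and 2 genes passed where 5 did without it (camera adjusted p = 1.5e-05). With the epithelial mean as a term it was 0.17 and the list passed (camera adjusted p = 0.042), but no single gene did. The mean of 10 feedback genes was higher in mutants by 0.21 (exact permutation p = 0.0079, two-sided, the smallest these arrays can give), yet 4 of 16 immediate early and heat shock genes rose too. The mean of all ERK targets already separated these arrays (6.28 to 6.46 in mutants, 5.91 to 6.24 in controls), so the p of the feedback genes adds little. The immediate early and heat shock list did not pass without controls 1 and 3 (camera adjusted p = 0.13), at a median of 0.13. Handling of the tissue and a response to genotype cannot be told apart here.

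The third pattern concerns genes with 2 separate levels among the E14.5 arrays. Wdfy1 lay at 4.30 to 4.69 in the 5 mutants, and 2 of the 5 controls (4.94 and 4.70) lay within 1 log2 unit of the mutant mean while the others were at 6.69 to 7.06. An allele that segregates among the embryos may account for Wdfy1. Including Wdfy1, 9 genes outside the sex-linked ones had such levels, at most 5 did in 100 simulated rounds, and 1 of the 9, Ifi202b, followed genotype. The simulated values were normal, so for the 9 genes ordinary variation with wider tails and segregating alleles cannot be told apart. For Ifi202b itself a linked allele and an effect of genotype were not tested against each other.

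Other splits of the same arrays show where chance can be excluded. Of 100 splits at E14.5 only the real one (1 split) called as many as 292 genes. The highest other called 118 and put all 4 batch 1 arrays on one side with control 5. The other drawn splits with those 4 arrays on one side called 0 genes, and 0 genes passed between the batches. With the batch term in the fit, such a split compares 1 batch 2 array with the others of batch 2, for the 118 control 5. Control 5 had the lowest 5' minus 3' signals of beta-actin (−1.61) and Gapdh (−0.58) at E14.5. Whether that accounts for the 118 was not tested. For the lists at E14.5, 3 of 100 splits gave as many as 11, and the highest other gave 12. For the difference between stages, 2 of 100 regroupings gave as many as 13 genes (highest other 13). As many as 12 lists came from 5 of 100 (highest other 16), so chance was not excluded for the lists. These regroupings mixed the genotypes at both stages at once, so they stand for no genotype effect at either stage. For the genes they therefore cannot say whether the effects differed between stages. For the correlation between stages, 2 of 100 regroupings of both stages reached 0.27 (3 in either sign), and the highest other was 0.38. With the E14.5 arrays alone regrouped, 6 of 100 reached it in either sign (highest other 0.29), and with the E13.5 arrays alone, whose 10 splits are too few, the highest other was 0.28. Counted in either sign, chance was excluded for the correlation in the first of these and not in the second. The second was not counted in 1 sign alone, where the verdict may differ. At E13.5 the 10 splits are too few for a share under 0.05: the real split called 11 genes and 14 lists, and the highest others 1 and 7. Without a batch term, only the real split (1 of 56) reached the stage counts of 9664 genes in controls (highest other 5204) and 9538 in mutants (highest other 1). For lists between stages, 37 of 56 splits gave as many as 6 in controls (highest other 12) and 16 of 56 gave as many as 8 in mutants (highest other 11), so chance was not excluded.

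Single E14.5 arrays far from the others of their group were found in 7 of 148 checks, and chance gives about 1 in 20. The gap to the nearest array, as a share of the range, was 0.858 for Phex and 0.805 for Dusp4 in control 1 (lowest), 0.767 for P4ha1 in mutant 2, 0.829 for Perp in mutant 5 and 0.836 for Myod1 in mutant 1 (highest). It was 0.779 for the mean of the osteogenic genes in mutant 2 (highest) and 0.744 for the Gapdh 5' minus 3' signal in control 5 (lowest).

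The effect of genotype differed between the stages for 13 genes, as a log2 difference: Ifi202b (1.93), Krt6a (0.94), Cwc22 (0.74), Sfn (0.74), Cxcl5 (0.70), Depdc7 (0.66), Dubr (0.65), Mpzl2 (0.64), Tmem132c (0.56), Ankrd29 (0.55), Socs3 (0.48), Commd9 (−0.56) and Gzmm (−0.45). Gzmm lay near the floor at E14.5, so its difference is not a measured change in effect. By camera, lists more positive at E14.5 were oral epithelium (adjusted p = 3.6e-12), ERK targets (1.9e-05) and cholesterol biosynthesis (0.017). Lists more negative at E14.5 were endothelium (1.9e-05), cartilage (2.5e-05), macrophages (4.1e-05), osteogenic (0.0031), erythroid (0.020), extracellular matrix (0.020), skeletal muscle (0.025), neurons (0.039) and Schwann cells (0.040). For the extracellular matrix the median difference was 0.04, above 0, while the test, which compares with all genes, was negative, and the median was −0.04 with each array centred. For Schwann cells the median was −0.10, and 0.02 after a further quantile normalization. The number of lists was 7 without E14.5 mutant 2, where all arrays gave 12. Oral epithelium, ERK targets, endothelium, cartilage and macrophages passed in each of the 16 fits that left out 1 array. The others passed in 15 (osteogenic), 13 (cholesterol biosynthesis and erythroid), 9 (extracellular matrix), 8 (Schwann cells) and 7 (neurons and skeletal muscle). After centring each array on its median 6 lists passed, without erythroid, extracellular matrix, neurons, osteogenic, Schwann cells and skeletal muscle. None of these lists passed with an estimated correlation (adjusted p of 0.22 or more). By fry, oral epithelium (adjusted p = 0.010), ERK targets (0.010) and cholesterol biosynthesis (0.030) passed. None of the lists more negative at E14.5 did (fry adjusted p of 0.33 or more). Camera sets them against all genes, whose median difference was 0.06.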

How the results depend on the processing

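The fits without controls 1 and 3, with sex and with the actin signal were chosen after the data were seen. No log2 change of a named gene turned under the alternatives where named genes were followed, which exclude the fit of each probe set by itself. Named genes were picked for large changes or small p in the main fit, so few were likely to turn. At E14.5, 1166 of 1527 values over 50 named genes stayed on their side of the threshold, 358 no longer passed and 3 newly passed. At E13.5 the numbers were 742, 74 and 4 of 820, and for the difference between stages 292, 145 and 5 of 442. For the named stage changes, 203 of 203 values in controls and 145 of 145 in mutants stayed. Leaving out each array gave 6 to 35 genes at E13.5, 105 to 262 at E14.5, 3 to 20 for the difference between stages, 9341 to 9638 for controls between stages and 9124 to 9541 for mutants. It gave 8 to 15 lists at E13.5, 8 to 11 at E14.5, 7 to 12 for the difference, 6 to 8 for controls and 7 to 8 for mutants, and a correlation between stages of 0.21 to 0.30. Other probe sets of the targeted gene, named beforehand for comparison, were not analysed here. Where a value below moved and no cause is given, the cause was not tested.

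With no filter on low values, which tests more genes, the counts were 184 at E14.5, 16290 in controls and 16152 in mutants between stages, with 11 and 13 lists and a correlation of 0.15. With the stricter filter, which tests fewer, they were 8 for the difference, 6178 and 6097 between stages, and 5 lists in mutants. The mean over probe sets gave 7 lists for the difference. A further quantile normalization gave 27 genes at E13.5 and 130 at E14.5, with 7 lists for the difference and 4 in mutants between stages. Median centring gave 6 lists for the difference. Array weights gave 85, 155 and 40 genes at E13.5, at E14.5 and for the difference. Without the batch term E13.5 had 20. E14.5 batch 1 alone gave 3 genes at E13.5, 31 at E14.5 and 6 for the difference, and batch 2 alone 128 at E14.5, 20 for the difference and a correlation of 0.16. Asking also for a 1.5-fold change left 46 at E14.5, 8 for the difference, and 6247 and 5921 between stages. The E14.5 arrays alone gave 64. Each probe set by itself gave 7 for the difference, 15722 and 15513 between stages. Genes called at either stage had a correlation of 0.40.

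Camera with an estimated correlation called 0 lists in each of the 5 contrasts, where the preset gave 14 at E13.5, 11 at E14.5, 12 for the difference, and 6 and 8 between stages. By fry the numbers were 4, 5, 6, 32 and 31. Sex as a term gave 143 genes and 7 lists at E14.5. Without E14.5 controls 1 and 3 there were 6 lists at E14.5 and 20 genes for the difference. The actin term gave 6 genes at E13.5 and 6 for the difference.

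With the replicate number as a block, E13.5 had 6 genes, E14.5 had 104 and the difference 3, and 98 of the 104 were among the 292. After group and batch effects were removed, same-numbered mutants and controls did not deviate together (correlations of −0.49 to 0.17). Of 8 mutants, 1 correlated best with its own number. This gave no sign of pairing, though a shared litter or processing cannot be excluded. Low signals limit the stage comparison.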

Other observations

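A few other groups differed little between genotypes at E14.5. Macrophage genes were lower in 12 of 19 cases (median −0.09, camera adjusted p = 0.025) and erythroid genes in 9 of 12 (median −0.12, camera adjusted p = 0.017), without a gene that passed. Cell cycle genes were higher in 24 of 31 cases by a median of 0.05 (camera adjusted p = 0.037). With an estimated correlation the adjusted p was 0.73, 0.40 and 0.70, and by fry it was 0.44, 0.15 and 0.10. None of the 3 passed without controls 1 and 3 (camera adjusted p = 0.38, 0.064 and 0.064). Macrophages did not pass without mutant 2 (0.40), control 1 (0.094), control 2 (0.057) or control 3 (0.11), nor cell cycle genes without mutant 2 (0.12), mutant 4 (0.11), control 2 (0.11) or control 3 (0.13). With sex as a term macrophages (0.19) and cell cycle genes (0.059) did not pass, and with the mean over probe sets none of the 3 did (0.066, 0.078 and 0.31). Nor did the cell cycle once each array was centred on its median (0.066). The components of the ERK cascade other than the targeted gene were not shifted at either stage (camera adjusted p = 0.62 and 0.89).

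At E13.5 the lists for Schwann cells (camera adjusted p = 6.5e-04), macrophages (0.0061) and the tricarboxylic acid cycle (0.011) were higher relative to other genes. Those for tooth tissue (0.0087) and the amino acid stress response (0.033) were lower. No member of these passed at E13.5 over all genes tested, and no list passed with an estimated correlation (adjusted p of 0.39 or more). None of these lists passed by fry (adjusted p of 0.08 or more). Without mutant 2 the macrophages (0.074) and tooth tissue (0.12) did not pass, and without control 3 neither did (0.078 and 0.18). The amino acid stress response did not pass without mutant 3 (0.14) or control 1 (0.075). With the actin signal as a term tooth tissue (0.057), the amino acid stress response (0.17) and the tricarboxylic acid cycle (0.091) did not pass. With no filter on low values Schwann cells (0.052), macrophages (0.28) and the tricarboxylic acid cycle (0.42) did not pass. Schwann cells did not pass after a further quantile normalization (0.13), nor the tricarboxylic acid cycle with the mean over probe sets (0.29). The amino acid stress response did not pass after either of quantile normalization (0.097) and centring (0.063), nor with the mean over probe sets (0.25).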
